A study of Homo sapiens with 6 samples.

How the data were processed

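HEK293FT cells received 1 of 3 guide RNA plasmids in 2 independent experiments each, 24 h after seeding, per the labels' protocols. Isolated RNA was annealed to a strand that pairs with the antisense portion of its guide, with 3 min at 95 °C, and repurified. Stranded poly(A)+ libraries were prepared from 200 ng. The growth protocol writes the line as HEK293DT and the other labels as HEK293FT.

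The authors deposited expected counts per gene symbol for each sample, made with RSEM and STAR per the submitters' processing notes. Their versions, the genome build and the annotation are not given in the sources used here. RSEM divides reads that match several genes between them, and 6.95% to 7.36% of the values in a library were not whole (tolerance 1e-09). Both libraries of a group listed the same genes, 11958 for the non-targeting, 12148 for the CLUSTER and 12233 for the LEAPER guide. Of 12403 genes listed anywhere, 605 were missing from at least 1 group. Mean counts of those 605 followed transcript length (Spearman's rho 0.803 across genes, against 0.0563 for genes listed everywhere), a pattern that a minimum on a length-scaled value would give, but no rule is stated. An unlisted gene is not a gene at 0, so these were not tested, and the totals are sums over listed genes rather than the full depth.

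Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. filterByExpr removed 3 of 11798 genes. Libraries were scaled with TMM, and all 6 entered a quasi-likelihood fit of 3 groups with 3 residual degrees of freedom. Calls had a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The biological coefficient of variation was 8.41%. Replicates differed beyond counting error in every group (chi-square per degree of freedom 8.56, 4.52 and 55.5 for the non-targeting, CLUSTER and LEAPER pairs), so replicate spread and not depth limits most genes. The median absolute log2 difference between replicates was 0.08, 0.05 and 0.21 in that order. When a library is left out, the lone sample of its group is assumed to vary like the other groups.

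Of 29 gene lists written before the data were examined, 24 had at least 3 measured members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry. With an estimated correlation camera also rests on the 3 residual degrees of freedom, so a list can fail there whatever its correlation. The heat shock and cholesterol synthesis estimates (-0.0154 and -0.0176) lay below the preset, and neither list passed with them. The other lists that camera called had estimates above the preset, from 0.0354 for the unfolded protein response to 0.780 for the ribosomal list. Among them the respiratory chain list had 0.381 and the histone list 0.266. For these lists the p values at the preset rest on a correlation lower than the one estimated from the data. ADAR enzymes, small structured RNAs and blood markers had 2 measured members each, of which edgeR called 0 over all genes tested (adjusted over the list alone, ADAR was higher with the LEAPER than the CLUSTER guide), and liver markers and mitochondrially encoded genes had 0 measured. Genes are named by a rule made before the data were examined: RAB7A and the ADAR genes, then per comparison up to 12 higher and 12 lower genes with the greatest change among called genes whose mean log2 CPM was at least 1 and whose libraries lay apart in both groups, and up to 4 members of lowest p of each list with a call or called members.

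Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom on unrounded counts, RLE, library-total and upper-quartile scaling, no filter or at least 50 counts in 2 libraries, thinning to the smallest total, fits of only the groups compared, a test against a fold change of 1.2, replicate number as a term (replicate block, which gave 3547, 4694 and 323 calls in the 3 comparisons) and leaving out each library. Added after the data were seen were a correction for GC content and length, with splines of 5 and 4 degrees of freedom per library, the same without LEAPER replicate 2, and fits of all genes listed in both groups compared. The correction used GENCODE release 29 transcripts for 11547 of 11795 genes (97.9%). Symbols matched exactly for 11526 genes and through older symbols for 596, and 281 had no match.

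The scripts were tested on simulated data for the CLUSTER comparison with 11547 genes, of which 200 were changed. edgeR recovered 78% of the genes changed 1.5-fold and 99% of those changed 2-fold, with 6 false calls among 183. With the libraries' GC and length trends added, and the smaller spread of the corrected fit, it recovered 59% and 96%, and the corrected fit 97% and 100%. Without trends the corrected fit recovered 78% and 99%. The settings with and without trends differ in spread, so their shares cannot be compared. The added trends were those that the correction estimates, so its recovery there does not test the correction independently.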

Results

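Poly(A)+ RNA was sequenced from HEK293FT cells, a human embryonic kidney line, 48 h after transfection of 1200 ng of plasmid encoding a guide RNA. The 3 groups received a non-targeting guide, a CLUSTER guide or a LEAPER guide, with 2 independent samples each. Both targeting guides are directed at the 3' untranslated region of the RAB7A transcript and recruit the cell's own ADAR enzymes, which convert adenosine to inosine in double-stranded RNA. The series asks about off-target editing and about changes in gene expression. Editing cannot be read from gene-level counts and was not analysed here. The expected counts of the listed genes summed to 48085844 and 44287168 in the non-targeting libraries, 51735817 and 43810616 in the CLUSTER libraries, and 48168589 and 52256401 in the LEAPER libraries. The 11798 genes listed in all 6 libraries were compared. Levels are given in CPM, counts scaled to library size.

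RAB7A, a small GTPase of late endosomes and the transcript targeted by both guides, was measured first. In GRCh38 with GENCODE release 29, matched by symbol, RAB7A (ENSG00000075785.12) lies on chromosome 3 from 128726122 to 128814796 on the plus strand. The 3' untranslated region of its matched transcript, 1374 nt in exon 6, spans 128813423 to 128814796. RAB7A stood at 237 ± 0.867 CPM (SD, n = 2) with the non-targeting guide, 194 ± 0.506 with the CLUSTER guide and 205 ± 9.79 with the LEAPER guide. With the CLUSTER guide RAB7A was 1.22-fold lower than with the non-targeting guide (log2 fold change -0.29, SE 0.074, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0281). The LEAPER estimate was -0.21 (SE 0.074) and missed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.0551). RAB7A differed between the LEAPER and CLUSTER guides by 0.08 (SE 0.074, edgeR, Benjamini-Hochberg adjusted p = 0.639). The CLUSTER call for RAB7A was lost without non-targeting replicate 1 or 2 (-0.29 and -0.28) and without CLUSTER replicate 1 or 2 (-0.29 and -0.29). The LEAPER estimate was -0.26 without LEAPER replicate 1 and -0.16 without LEAPER replicate 2. Over alternatives that leave out no single library, the CLUSTER adjusted p ran from 0.00013 to 0.031 (edgeR, DESeq2 or limma-voom, Benjamini-Hochberg). The LEAPER adjusted p ran from 0.0103 to 0.133 over the same alternatives and tests. Neither range includes the test against a fold change of 1.2, for which no RAB7A result is given.

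**Figure D1:**
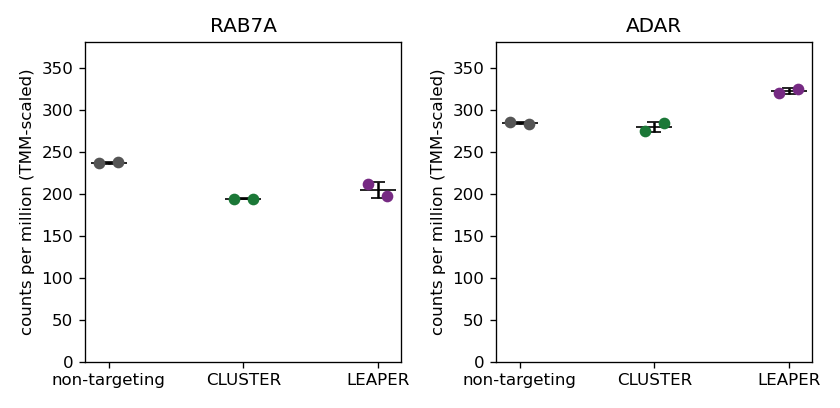
Levels of RAB7A and ADAR in CPM after TMM scaling (vertical axes, from 0) in the 3 groups (horizontal axes); points are libraries and black bars the mean and SD of 2 libraries. RAB7A lies at 237 with the non-targeting guide, 194 with the CLUSTER guide and 205 with the LEAPER guide.

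ADAR, an adenosine deaminase that edits double-stranded RNA, was not called in any of the 3 comparisons. Its level was 284 ± 1.64 CPM (SD, n = 2) with the non-targeting guide, 279 ± 6.20 with the CLUSTER guide and 322 ± 3.77 with the LEAPER guide. The LEAPER estimate against the non-targeting guide was 0.18 (log2, SE 0.070, edgeR, Benjamini-Hochberg adjusted p = 0.0733). After a correction for GC content and length added once the data had been seen, ADAR passed against both other guides (0.14 and 0.19). ADARB1, the other catalytically active family member, stood at 28.7 ± 0.286, 30.1 ± 1.01 and 28.4 ± 2.08 CPM in the same order and was not called.

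The CLUSTER guide was compared with the non-targeting guide to find differences beyond the target. DHRS2, a short-chain dehydrogenase, rose 2.92-fold (log2 1.55, SE 0.13), from 3.62 to 10.6 CPM (n = 2 each). PVT1, a long non-coding RNA next to MYC, rose 2.69-fold (log2 1.43, SE 0.11), and LRP5L rose by 1.22 on the log2 scale (SE 0.11). UHMK1, a serine/threonine kinase, fell by 1.12 on the log2 scale (SE 0.20), from 76.2 to 35.1 CPM. MSMO1, an enzyme of cholesterol synthesis, fell by 1.07 (SE 0.25), the adhesion molecule CD58 by 1.21 (SE 0.31) and the amino acid transporter SLC38A2 by 0.95 (SE 0.20). HNRNPA1P10 at 2.49, PRR4 at 1.87 and H3F3A at -1.69 also passed, but fractional counts in all 6 libraries mark reads shared with similar genes and make these values uncertain. Without non-targeting replicates 1 and 2 DHRS2 and PVT1 missed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.0616 and 0.0507), as did UHMK1 (0.0715 and 0.114), MSMO1 (0.0785 and 0.157), CD58 (0.0792 and 0.177) and SLC38A2 (0.0792 and 0.131). Without CLUSTER replicates 1 and 2 the values were 0.0744 and 0.111 for UHMK1, 0.0922 and 0.163 for MSMO1, 0.122 and 0.156 for CD58 and 0.0922 and 0.145 for SLC38A2 (edgeR, Benjamini-Hochberg adjusted p). In all, 1487 genes were higher and 1293 lower among 11795 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2211 higher and 707 lower when scaled by library totals alone. The edgeR count was 0 without non-targeting replicate 1 and 0 without replicate 2 (3349 and 2509 genes at an unadjusted p under 0.05), 58 and 23 without CLUSTER replicates 1 and 2, and 6832 and 6840 without LEAPER replicates 1 and 2, while DESeq2 on all libraries called 3279 and limma-voom 2677.

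Some members of the ribosomal, heat shock and respiratory chain lists, fixed before the data were examined, fell with the CLUSTER guide, and most members were not called. Of 79 ribosomal protein genes, 25 fell and 0 rose (26 and 0 adjusted over the list alone), with RPL7 at -0.58 (log2, SE 0.068) and RPL9 at -0.50 (SE 0.067). Of 65 respiratory chain genes, 16 fell and 1 rose (21 and 1 adjusted over the list alone), with SDHC at -0.56 and COX7A2 at -0.48. Of 19 heat shock genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone), among them the chaperones HSP90AA1 at -0.47 and HSPA8 at -0.36. Of 21 genes of the unfolded protein response, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with PDIA6 at -0.46 and HSPA5 at -0.43. Of 35 ATF4 targets of the integrated stress response, 10 rose and 1 fell (11 and 2 adjusted over the list alone), with CHAC1 at 0.61 and SESN2 at 0.53. Of 18 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with HIST1H2AC at 1.17. Of 363 ZNF-named genes, 77 rose and 7 fell (76 and 7 adjusted over the list alone), with ZNF485 at 0.82 and ZNF416 at 0.73. These 7 lists passed camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p from 2.6e-08 to 0.0451). None passed camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.621 to 0.645). The estimate for the heat shock list was -0.0154, below the preset, so correlation between its genes does not account for that loss. The ribosomal and respiratory chain lists had estimates of 0.780 and 0.381, well above the preset. With fry, which tests direction without reference to other genes, of these lists only the heat shock list passed (Benjamini-Hochberg adjusted p = 0.0258), and the ribosomal and respiratory chain lists did not (0.174 and 0.162). The camera call of the unfolded protein response list was lost without non-targeting replicate 2, without CLUSTER replicate 1 and without either LEAPER replicate. It was also lost with the replicate block and in a fit of only the groups compared (camera, Benjamini-Hochberg adjusted p = 0.0641 in the latter). That of the ATF4 targets was lost without non-targeting replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.114), without CLUSTER replicate 2 (0.0573) and after the correction for GC content and length (0.0551). Without non-targeting replicate 1 or 2 the edgeR calls of these genes went with the 0 called in all, where 3349 and 2509 genes had an unadjusted p under 0.05, and 58 and 23 genes were called without CLUSTER replicates 1 and 2; with all libraries DESeq2 called 3279 and limma-voom 2677.

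The other lists were not called by camera for the CLUSTER guide before correction for GC content and length. Of 27 interferon-stimulated genes, PARP12 (0.69), IRF7 (0.49) and USP18 (0.31) rose and EIF2AK2, the kinase PKR that binds double-stranded RNA, fell by 0.42 on the log2 scale (1 and 0 adjusted over the list alone). Of 48 RAB7A partners and late endosome genes, 1 rose and 8 fell (1 and 7 adjusted over the list alone), with VPS11 at 0.49 and RAB5B at -0.51. Of 45 lysosomal genes, 6 rose and 14 fell (6 and 19 adjusted over the list alone), with the regulator TFEB at 0.58. Of 23 cholesterol synthesis genes, 2 rose and 8 fell (2 and 10 adjusted over the list alone). After the correction camera with the preset correlation called the lysosomal list lower (26 of 45 genes lower, Benjamini-Hochberg adjusted p = 0.000108) and the cholesterol synthesis list lower (14 of 23 lower, 0.00390), neither with the correlation taken from the data (adjusted p = 0.2998 and 0.389 with an estimated correlation). Without the correction the cholesterol synthesis list passed fry, lower (Benjamini-Hochberg adjusted p = 0.0383). Members higher and lower numbered 1 and 0 of 6 NF-kappaB genes, 4 and 0 of 18 p53 targets, 2 and 1 of 27 immediate early genes, 2 and 5 of 31 autophagy genes and 2 and 5 of 28 hypoxia genes. They numbered 6 and 3 of 29 S phase genes, 2 and 0 of 30 G2 and M phase genes, 1 and 1 of 5 nuclear-retained RNAs, 3 and 3 of 33 factors that bind double-stranded RNA or degrade RNA, 2 and 2 of 16 known ADAR recoding targets and 3 and 1 of 13 neighbours of RAB7A in 3q21. Of 6 fibroblast markers 1 was higher and 0 lower, and of 6 markers of epithelial carcinoma 0 were higher and 1 lower. Adjusted over the list alone, the counts higher and lower in the same order were 0 and 0, 4 and 0, 0 and 0, 2 and 5, 2 and 7, 6 and 3, 0 and 0, 1 and 1, 2 and 2, 2 and 2, 3 and 1, 1 and 0, and 0 and 1. After the correction for GC content and length, members higher and lower numbered 1 and 11 of the immediate early genes (median -0.14) and 5 and 4 of the p53 targets (median 0.08 before and -0.04 after). They numbered 8 and 1 of the G2 and M phase genes (-0.14 before and 0.04 after) and 4 and 3 of the 3q21 neighbours (0.08 before and -0.03 after). ADAR recoding targets then numbered 2 and 7, and interferon-stimulated genes 4 and 4. Factors that bind double-stranded RNA or degrade RNA numbered 11 and 6 (-0.02 before and 0.03 after). Medians also changed sign for the NF-kappaB genes (0.14 before and -0.0044 after) and the fibroblast markers (0.05 before and -0.14 after). Camera with the preset correlation called none of these lists after the correction. Calls of these genes too went with the 0 left by edgeR without non-targeting replicate 1 or 2 (3349 and 2509 at an unadjusted p under 0.05; DESeq2 3279 and limma-voom 2677 with all libraries), and 58 and 23 genes were called without CLUSTER replicates 1 and 2.

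The LEAPER guide was compared with the same non-targeting libraries. DHRS2 rose by 2.06 on the log2 scale (SE 0.13), to 15.1 CPM (n = 2), and PVT1 by 1.67 (SE 0.11). ZNF346, which encodes a zinc finger protein that binds double-stranded RNA, rose by 1.56 (SE 0.11), from 22.2 to 65.8 CPM, and AP3B2, an adaptor subunit, by 1.54 (SE 0.12). UHMK1 fell by 1.47 (SE 0.20), the paraoxonase PON2 by 1.26 (SE 0.16), TMEM9B by 1.18 (SE 0.11) and TWF1, an actin-binding protein, by 1.10 (SE 0.17). PRR4 at 2.39, SLC2A3 at -1.09 and H3F3A at -2.03 also passed, with fractional counts in all 6 libraries that leave them uncertain. In all, 2312 genes were higher and 1893 lower among 11795 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3031 higher and 1240 lower when scaled by library totals alone. The count was much lower without either non-targeting library, lower without either CLUSTER library and higher without either LEAPER library.

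More ribosomal, respiratory chain, heat shock and lysosomal genes fell than rose with the LEAPER guide, and many were not called. Of 79 ribosomal protein genes, 50 fell and 0 rose (62 and 0 adjusted over the list alone), with RPL7 at -0.69 (log2, SE 0.068) and RPS4X at -0.64 (SE 0.074). Of 65 respiratory chain genes, 31 fell and 2 rose (34 and 2 adjusted over the list alone), with SDHC at -0.70. Of 19 heat shock genes, 10 fell and 0 rose (11 and 0 adjusted over the list alone), with DNAJB1 at -0.55 and HSP90AA1 at -0.53. Of 45 lysosomal genes, 23 fell and 4 rose (23 and 6 adjusted over the list alone), with PSAP at -0.49 and TFEB at 0.67. Of 21 genes of the unfolded protein response, 9 fell and 1 rose (9 and 2 adjusted over the list alone), with HSPA5 at -0.60. Of 23 cholesterol synthesis genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone). Of 18 histone genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with HIST1H2AC at 1.72, and of 363 ZNF-named genes 124 rose and 9 fell (130 and 9 adjusted over the list alone). These 8 lists passed camera with a preset correlation (Benjamini-Hochberg adjusted p from 9.2e-16 to 0.0395), and none with the correlation taken from the data (adjusted p = 0.400 to 0.495 with an estimated correlation). Of these lists fry passed 6, and not the ribosomal and respiratory chain lists (Benjamini-Hochberg adjusted p = 0.0595 and 0.0530). The camera calls of the unfolded protein response and cholesterol synthesis lists were lost without LEAPER replicate 2 (Benjamini-Hochberg adjusted p = 0.0992 for both), the latter also without non-targeting replicate 1 (0.0668) and with library totals (0.0537). Over all genes the edgeR count fell strongly without either non-targeting library, fell less without either CLUSTER library and rose without either LEAPER library.

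The interferon list was not called for the LEAPER guide (camera, Benjamini-Hochberg adjusted p = 0.672). Of its 27 measured genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with PARP12 at 1.10, USP18 at 0.66 and TRIM21 at -0.47. Without non-targeting replicates 1 and 2 TRIM21 missed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.129 and 0.0632). Of 48 RAB7A partners and late endosome genes, 5 rose and 9 fell (4 and 8 adjusted over the list alone), with UVRAG at 0.87 and RAB5B at -0.83. Of 35 ATF4 targets, 13 rose and 3 fell (14 and 4 adjusted over the list alone), with SESN2 at 0.78. Of 30 G2 and M phase genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with the mitotic kinase PLK1 at 0.87. Of 33 factors that bind double-stranded RNA or degrade RNA, 6 rose and 5 fell (6 and 4 adjusted over the list alone), with the microRNA processing proteins DROSHA at 0.56 and DGCR8 at -0.55. Members higher and lower numbered 2 and 0 of 6 NF-kappaB genes, 4 and 3 of 18 p53 targets, 3 and 3 of 27 immediate early genes, 3 and 10 of 31 autophagy genes, 5 and 8 of 28 hypoxia genes and 8 and 7 of 29 S phase genes (2 and 0, 5 and 3, 3 and 1, 3 and 11, 6 and 8, and 8 and 7 adjusted over each list alone). They numbered 1 and 1 of 5 nuclear-retained RNAs, 1 and 3 of 16 known ADAR recoding targets, 3 and 2 of 13 neighbours of RAB7A in 3q21, 2 and 1 of 6 fibroblast markers and 0 and 2 of 6 markers of epithelial carcinoma (1 and 1, 0 and 1, 3 and 2, 2 and 1, and 0 and 2 adjusted over each list alone). Of the lists not called by camera, fry passed the RAB7A partners and late endosome list (Benjamini-Hochberg adjusted p = 0.0475), autophagy (0.0395), hypoxia (0.0406) and the carcinoma markers (0.0164, median -0.23), all lower. After the correction for GC content and length camera with the preset correlation called the G2 and M phase list higher (Benjamini-Hochberg adjusted p = 0.00325), not so with the correlation taken from the data (adjusted p = 0.397 with an estimated correlation). Its members higher and lower then numbered 18 and 2. Immediate early genes numbered 5 and 10, ADAR recoding targets 3 and 8 and interferon-stimulated genes 9 and 6, lists that camera did not call. Over all genes the count fell strongly without either non-targeting library, fell less without either CLUSTER library and rose without either LEAPER library.

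The LEAPER and CLUSTER guides were then compared directly. ZNF346 was higher with the LEAPER guide by 1.45 on the log2 scale (SE 0.11), TOR1B, a torsin ATPase, by 1.28 (SE 0.10), KANK1 by 0.99 (SE 0.10) and EXO1, an exonuclease of DNA repair, by 0.98 (SE 0.088). UVRAG was higher by 0.89 (SE 0.10) and the stress transcription factor ATF3 by 0.62 (SE 0.090). CASS4 stood at -0.70 (SE 0.11) and RNF4, a ubiquitin ligase, at -0.61 (SE 0.078), both past the test. Of 30 G2 and M phase genes, CCNA2 rose by 0.75 and PLK1 by 0.56, and 0 fell (2 and 0 adjusted over the list alone). Of 363 ZNF-named genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). No ribosomal, respiratory chain or heat shock gene passed edgeR's test (0 and 0 adjusted over each list alone), and of 45 lysosomal genes GUSB rose by 0.54 and 0 fell (1 and 0 adjusted over the list alone). Camera with a preset correlation called the G2 and M phase and ZNF-named lists higher and the other 4 lower (Benjamini-Hochberg adjusted p from 9.0e-11 to 0.0360), none with the correlation taken from the data (adjusted p = 0.593 with an estimated correlation) and 0 lists without LEAPER replicate 2 (Benjamini-Hochberg adjusted p from 0.0565 to 0.330). After the correction for GC content and length edgeR called 3 ribosomal genes higher and 8 lower, 2 and 5 of the respiratory chain, 0 and 2 of the heat shock list and 1 and 8 lysosomal genes. It called 8 G2 and M phase genes higher and 1 lower, and 48 and 9 ZNF-named genes. The ZNF-named list was then not called (camera, Benjamini-Hochberg adjusted p = 0.1501, median 0.03 against 0.07 before). The heat shock list was lost in 8 of 18 alternatives, among them without non-targeting replicates 1 and 2 (camera, Benjamini-Hochberg adjusted p = 0.0507 and 0.0514), CLUSTER replicate 1 (0.0743) and LEAPER replicate 1 (0.0696). Without CLUSTER replicates 1 and 2 all edgeR calls of genes were lost, with values of 0.122 and 0.166 for ZNF346 and TOR1B and 0.165 and 0.196 for KANK1 and EXO1 (edgeR, Benjamini-Hochberg adjusted p). Without non-targeting replicates 1 and 2 calls were lost for CASS4 (0.0752 and 0.0750), RNF4 (0.0564 and 0.0553), ATF3 and CCNA2 (0.0586 and 0.0573), PLK1 (0.0886 and 0.0882) and GUSB (0.0973 and 0.0956; edgeR, Benjamini-Hochberg adjusted p). In all, 174 genes were higher and 11 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), a split of 163 and 10 with limma-voom that moved to 326 and 82 with DESeq2, 1208 and 719 after the correction for GC content and length, 2733 and 2613 without LEAPER replicate 1 and 849 and 307 without LEAPER replicate 2. There were 1834 genes at an unadjusted p under 0.05, 408 called by DESeq2 and 173 by limma-voom. The edgeR count was 43 and 44 without non-targeting replicates 1 and 2, 0 and 0 without CLUSTER replicates 1 and 2 (717 and 679 genes at an unadjusted p under 0.05), and 5346 and 1156 without LEAPER replicates 1 and 2.

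Fold changes of both targeting guides against the shared non-targeting libraries were compared over genes. DHRS2 and PVT1 rose, and UHMK1 and PON2 fell, in both comparisons. Across 11795 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.844 and Spearman's rho = 0.832. In 100 simulated data sets of unchanged groups with the same controls, drawn independently per gene and without library GC trends, r averaged 0.503. The covariance was 0.0976, against a simulated mean of 0.00837, a difference of 0.0892. The simulated mean leaves out GC trends of the shared non-targeting libraries, so part of this difference may come from them. After the correction for GC content and length the covariance was 0.0734, against a simulated 0.00341, a difference of 0.0700. Over all 11795 genes 82.5% had the same sign in both comparisons, against a simulated mean of 66.7%. Among genes called in both comparisons, 1239 were higher and 1037 lower, and 2 moved in opposite directions, where independent lists would share 291 and 208. Without LEAPER replicate 1 299 genes moved in opposite directions, and after the correction for GC content and length 20 did. Part of the excess may come from the shared controls. Without LEAPER replicate 1, r was 0.650, without non-targeting replicate 1 or 2 0 genes were called in both by edgeR, as 0 were called for the CLUSTER guide (3349 and 2509 at an unadjusted p under 0.05, DESeq2 3279 and limma-voom 2677 with all libraries), and without CLUSTER replicates 1 and 2 58 and 23 were, against 3964 and 6018 without LEAPER replicates 1 and 2.

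**Figure D2:**
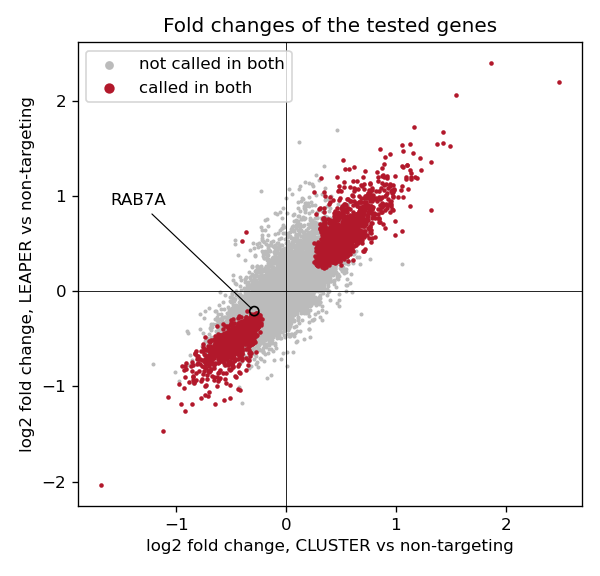
Log2 fold change against the non-targeting guide with the CLUSTER guide (horizontal axis) and the LEAPER guide (vertical axis) for 11795 genes; red points passed edgeR's test in both comparisons and the open circle marks RAB7A. The points follow a rising diagonal, with r = 0.844.

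Genes of low and high transcript GC content differed between libraries. Genes of at most 40% GC, 1599 in number, had a median 0.10 and 0.24 above the mean of the 6 libraries (log2) in non-targeting replicates 1 and 2. The same genes lay at -0.09 and -0.18 in the CLUSTER libraries, at -0.23 in LEAPER replicate 1 and at 0.16 in LEAPER replicate 2. Across 11547 genes with a matched transcript, Spearman's rho between GC content and fold change was 0.625 for the CLUSTER guide, 0.322 for the LEAPER guide, and -0.424 for the LEAPER against the CLUSTER guide. Ribosomal protein genes kept a median of -0.16 and -0.26 for the CLUSTER and LEAPER guides after correction for GC content and length, and ZNF-named genes 0.18 and 0.27.

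**Figure D3:**
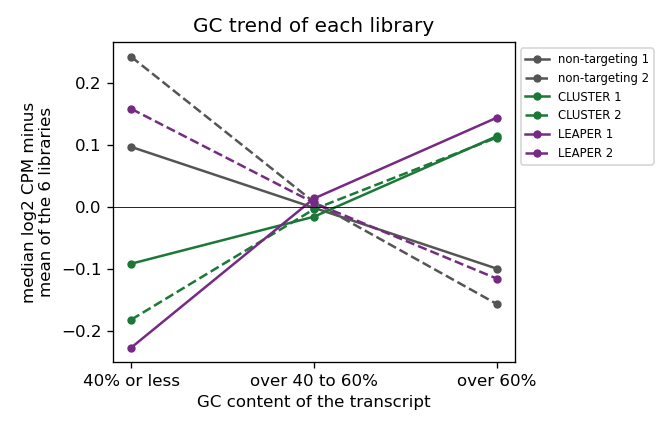
Median log2 CPM of each library minus the mean of the 6 libraries (vertical axis) for genes of low, middle and high transcript GC content (horizontal axis); colours are groups, and solid and dashed lines are replicates 1 and 2. LEAPER replicate 1 lies at -0.23 and LEAPER replicate 2 at 0.16 for the genes of lowest GC content.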

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

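The comparison of gene listings between groups was chosen after the data were seen. Some genes are listed for some groups only and enter no comparison. There were 254 genes listed with both targeting guides and not with the non-targeting guide, and 74 listed with the non-targeting guide and with neither targeting guide. The 5 of the first set with the highest level, named after their values were seen, include LRP1, a lipoprotein receptor, at 22.3 CPM of the listed total, without TMM scaling (mean, n = 2), with the CLUSTER guide and 28.4 with the LEAPER guide. On the same scale ONECUT2 stood at 19.6 and 24.4, BSN at 22.1 and 20.2, ZFHX4 at 17.2 and 19.3 and NBPF10 at 17.3 and 21.3. No level is given for them in the non-targeting libraries, and no fold change was computed. Across the 254 genes mean counts followed transcript length (Spearman's rho 0.789). Their median was 1.39 CPM per kb of transcript, against 12.7 for genes listed in all groups. A high CPM in this set can therefore reflect a long transcript, and a missing listing is not a level of 0.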

How the results depend on the processing

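The GC and length correction, with and without LEAPER replicate 2, and the fits of all genes listed in both groups were chosen after the data were seen. Counts of called genes stayed within 1.5 times the reported count for the CLUSTER and LEAPER guides against the non-targeting guide with DESeq2, limma-voom, the 3 other scalings, both filters, thinning and the replicate block (3547 and 4694). The LEAPER against CLUSTER count of 185 moved with DESeq2 to 408 and with the replicate block to 323, and the cause was not tested. Fits of only the groups compared called 6836, 2717 and 49 genes for CLUSTER and LEAPER against the non-targeting guide and LEAPER against CLUSTER, and with all genes listed in both groups 6860, 2711 and 52. RAB7A's SE was 0.0389 in the fit of the CLUSTER and non-targeting groups, and 0.0915 and 0.0881 in the fits with the LEAPER pair. It was 0.074 in the fit of all groups. The LEAPER replicates differ most. The same CLUSTER and non-targeting libraries gave 2780 calls in the fit with the LEAPER pair and 6836 without it, all 2780 among them. The CLUSTER count was thus lower when the LEAPER pair entered the fit. How far the spread of that pair accounts for the other counts was not tested. A test against a fold change of 1.2, stricter by construction, left 294, 1490 and 37. The GC and length correction gave 4870, 6793 and 1927, and without LEAPER replicate 2 6272, 7238 and 2257. It lowered the biological coefficient of variation from 8.41% to 4.53%.

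Leaving out each library gave 0 to 6840 genes for the CLUSTER guide, 1152 to 7386 for the LEAPER guide and 0 to 5346 for LEAPER against CLUSTER. The CLUSTER count was 0 in edgeR without non-targeting replicate 1 and without replicate 2 (3349 and 2509 at an unadjusted p under 0.05), and the direct count 0 without CLUSTER replicate 1 and without replicate 2 (717 and 679). With all libraries DESeq2 called 3279 and 408 and limma-voom 2677 and 173. Where a non-targeting or CLUSTER library is left out, the lone sample of its group takes its spread from the remaining pairs, the LEAPER pair among them. How much each pair adds was not measured.

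RAB7A kept its direction in every alternative run. For the CLUSTER guide leaving out each library gave -0.29 to -0.28, and the call was lost without any single non-targeting or CLUSTER library. For the LEAPER guide RAB7A passed with RLE size factors (-0.22), upper-quartile scaling (-0.21), the GC and length correction (-0.17) and that correction without LEAPER replicate 2 (-0.11). Leaving out each library gave -0.26 to -0.16. Between LEAPER and CLUSTER RAB7A passed only with the correction without LEAPER replicate 2 (0.12), and leaving out each library gave 0.03 to 0.13.

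With an estimated correlation camera called 0, 0 and 0 gene lists in place of 7, 8 and 6. That setting also rests on 3 residual degrees of freedom, so these losses do not measure correlation between genes alone. Fry, which tests direction without reference to other genes, called 2, 10 and 0, of which 1, 6 and 0 were among the lists camera called. The ribosomal and respiratory chain lists failed fry in every comparison. Of 18 alternatives the unfolded protein response list of the CLUSTER guide was lost in 8, the replicate block among them (camera, Benjamini-Hochberg adjusted p = 0.0504), and the ATF4 list in 6. For LEAPER against CLUSTER 3 lists were called after the correction without LEAPER replicate 2 and 0 to 6 when each library was left out. No list called in a comparison changed direction in an alternative run. The correlation of both guides' fold changes was 0.650 to 0.917 when each library was left out, lowest without LEAPER replicate 1.

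Among 309 named results the following estimates, none of them called as reported, changed sign. With library totals ADAR was at 0.0272 for the CLUSTER guide, and for the LEAPER guide ADARB1 at 0.0512, NFKBIA at 0.0316 and NEAT1 at 0.00185. For the CLUSTER guide, after the GC and length correction and after the same without LEAPER replicate 2, ADARB1 was at -0.0252 and -0.0253, NFKB2 at -0.0340 and -0.0336, MALAT1 at 0.0677 and 0.0669, COL1A1 at -0.00415 and -0.00480, COL5A1 at -0.0705 and -0.0701, and CAV1 at 0.0117 and 0.0122. For the LEAPER guide under both corrections COL1A1 was at -0.0536 and -0.0368 and ANXA1 at 0.104 and 0.330, and MALAT1 was at 0.00623 without LEAPER replicate 2. The last ANXA1 value alone passed edgeR's test (Benjamini-Hochberg adjusted p = 0.00683). Leaving out each library for the LEAPER guide gave -0.0935 to 0.0559 for ADARB1, -0.102 to 0.0303 for NFKBIA, -0.162 to 0.0352 for NEAT1 and -0.0214 to 0.244 for COL1A1. The cause was not tested.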

Other observations

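The GC and length correction and the pseudogene class were chosen after the data were seen, while the outcome each test would need was written before its value was seen. How the spread of the RAB7A share and the pseudogene median was weighed was settled after their values were seen.

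Many transcribed unprocessed pseudogenes, gene copies that are still transcribed, rose with both targeting guides, and the class was not tested against other genes. Of 84 measured, 41 rose and 0 fell with the CLUSTER guide (median log2 fold change 0.42, SE 0.050) and 49 rose and 0 fell with the LEAPER guide (median 0.51, SE 0.055). Without non-targeting replicate 1 or 2 edgeR called 0 of all genes for the CLUSTER guide (3349 and 2509 at an unadjusted p under 0.05, DESeq2 3279 and limma-voom 2677 with all libraries), and 58 and 23 without CLUSTER replicates 1 and 2. GC and length trends are unlikely to account for the class median, since 99.7% of its LEAPER median was kept after the correction (spread 10.7). Reads shared with parent genes cannot be told apart from a change of the pseudogenes, because the 20 with whole counts, of which 7 rose with each guide, had a LEAPER median of 0.3052 (SE 0.094), within its error of the 0.3 required beforehand, and a biological difference between guides stays open and untested.

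The broad change against the non-targeting guide was weighed against technical trends. After the GC and length correction 83.74% of the genes called with the CLUSTER guide and 94.36% of those called with the LEAPER guide were called in the same direction, so these trends are unlikely to be the whole cause. The corrected fit also had a smaller biological coefficient of variation (4.53% against 8.41%). It called 4870 and 6793 genes, against 2780 and 4205 before, which raises the share kept. That share does not measure how much of each change the trends make up. Depth is unlikely too, since 4189 genes were called with the LEAPER guide after thinning to the smallest library, against 4205 before. The guide itself and the strand added to each RNA are confounded with group and stay open. Whether an unrecorded library batch followed group is not known, and it stays open too. CLUSTER counts fell to 0 without either non-targeting replicate in edgeR (3349 and 2509 at an unadjusted p under 0.05, DESeq2 3279 and limma-voom 2677 with all libraries) and to 58 and 23 without CLUSTER replicates 1 and 2, and LEAPER counts to 1476 and 1152 without non-targeting replicates 1 and 2.

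RAB7A had a mean log2 fold change of -0.25 over both guides and -0.20 after the GC and length correction, which kept 79.84% of it (spread 18.7). That met the 75% required beforehand, but by less than its spread, so the share cannot decide whether these trends are the cause. After the correction RAB7A was still lower with the CLUSTER and LEAPER guides (-0.23 and -0.17, edgeR, Benjamini-Hochberg adjusted p = 0.00442 and 0.0103). The SE was also smaller there (0.047 against 0.074), which makes the test easier to pass, so the calls do not settle the question either. A change of the whole 3q21 neighbourhood is unlikely, as 13 neighbours had a median of 0.07427 (SE 0.095), though their median was -0.03 with the CLUSTER and -0.04 with the LEAPER guide after the correction, where this test was not repeated. Without the correction the CLUSTER call was lost without non-targeting replicate 1 or 2 (edgeR, Benjamini-Hochberg adjusted p = 0.155 and 0.220) and without CLUSTER replicate 1 or 2 (0.200 and 0.239). Whether the strand added to each RNA affected RAB7A reads was not tested, and a biological effect of the guides stays open.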
